A study of Zea mays with 36 samples.

How the data were processed

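RNA was measured in the leaf tip of field-grown maize (Zea mays) held under weed, low nitrogen or shade stress. Per the labels, each biological sample pooled the uppermost 8 cm of the youngest full-grown leaf from 4 plants. All plants were harvested at the V8 stage, a vegetative stage named for the number of leaves with a visible collar. There were 6 groups of 3 biological samples: control, low nitrogen, canola removed at V4, canola kept to V8, shade removed at V4 and shade kept to V8. The plots formed a randomized complete block layout, and the labels give the field replications as 3 in the sample descriptions and as 4 in the growth protocol. The replicate numbers were used as the labels give them, as field replications of separate plots. For 1 of the 2 labellings of canola kept to V8 replicate 3 the title gives no number, which was taken from the plot code in the file name.

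Per the labels, total RNA was extracted with Trizol, cleaned on RNeasy MinElute columns, amplified as aminoallyl RNA and labelled with Alexa 647 or Alexa 555. Each biological sample was labelled once with each dye and hybridised on a pair of arrays, so that 18 samples gave 36 channels on 18 arrays of a maize long-oligonucleotide chip in a loop with balanced dye swaps. Hybridisations fell on 9 days.

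The intensity of each spot and of its local background in both channels was deposited as GenePix Pro scanner output, with no normalization applied, per the file headers. The percent of a spot's pixels brighter than background and the percent of saturated pixels were read from the same deposited scanner files. The scanner software's spot flags were taken as given, per the file headers. The deposited files were 36 in number and held 18 distinct arrays, each given once for either dye; every array was used once. On 1 array the column headed as the red median held spot diameters, so spot mean intensities were used on every array. The authors' value table of the series, deposited as a unitless score per probe and sample, was compared with the scanner channels and used in no comparison, for the reason given with the alternatives. Its columns had medians from -0.302 to -0.115 and SDs from 0.997 to 1. What scale its values had before that standardisation, whether probes were centred, and in which direction each ratio ran remained unknown, and the software behind it is not given in the sources used here.

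Background was corrected with the normexp method at an offset of 50. Arrays were normalized within by loess and between by Aquantile, and control spots (2592) were given no weight in loess and left out afterwards. Spots the scanner software had marked as bad were left out, which with missing spots removed 0.672% of channel values. Replicate spots of a probe were averaged and different probes of a gene were kept apart. The array carried 43393 probes, of which 43390 could be tested and 39712 had a value in every channel. An annotation text was given in the files for 34185 probes (78.8%); 6 probes matched the reference table of gene names, so genes are named by the array's own, older annotation with the probe identifier beside them. No genome coordinates were used here.

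A first stage estimated each biological sample's value from its 2 channels by generalised least squares, with a random array effect and a dye term. A second stage fitted the 6 group means with the covariance this implies, using variance ratios of 6.19 for arrays and 0.204 for samples pooled over probes, and limma's empirical Bayes step gave the moderated test. There were 12 residual degrees of freedom between samples and 6.24 prior degrees of freedom. The threshold was an adjusted p of 0.05 after Benjamini-Hochberg correction over all probes of a comparison. All values are log2 fold changes with their standard error (SE), and group levels are means of normalized log2 intensity with the SD over 3 samples. A fitted change weights samples by the loop layout, so it can differ from the difference of the group means. A sample counts as showing a direction when its value lay on that side of the other group's mean. The 9 comparisons were each stress against control, canola kept against removed, shade kept against removed, and canola kept to V8 against shade kept to V8 and against low nitrogen. Software was R 4.3.3 with limma 3.58.1, statmod 1.5.0 and the data.table package at version 1.17.8.

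The comparisons, the tests, 32 gene lists, the rule for named genes and all but 2 of the alternatives were fixed before the data were examined. The lists were matched on annotation text: nitrogen assimilation, C4 cycle, Calvin cycle, light harvesting, photosystems and electron transport, chlorophyll and carotenoid synthesis, phytochrome and shade signalling, auxin, gibberellin with brassinosteroid and cytokinin, ethylene, jasmonate and lipoxygenase, abscisic acid with dehydrins, defence, benzoxazinoids, phenylpropanoids and flavonoids, glutathione transferases, antioxidant enzymes, sucrose and starch, senescence and proteolysis, circadian clock, cytosolic ribosome, chloroplast translation, heat shock and chaperones, phosphate and sulphate, aquaporins, cell wall and growth, and mitochondrial respiration. A further 5 lists marked other cell types: dividing cells, epidermis and cuticle, vascular and lignified cells, pollen and seed, and root. The benzoxazinoid list matched 0 probes and gave no result, which left 31 lists of at least 10 probes. Lists were tested with camera of limma at a preset correlation between genes of 0.01 on probes with complete values, with adjustment over the lists of a comparison. With an estimated correlation, the alternative, 0 lists passed in any comparison. In addition, member probes were adjusted over the list alone.

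Named probes were chosen by rule. Up to 10 probes with the largest rise and 10 with the largest fall were taken among those past the threshold, 1 per gene name. Where a direction had under 5 such probes, the 5 with the smallest unadjusted p were named and given as not past it. Up to 4 members with the smallest p were added for each list that passed its test.

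Whether samples with the same replicate number deviate together was checked on their deviations from the group means. The mean correlation was 0.431 for pairs sharing a number and -0.214 for other pairs. Deviations sum to 0 within a group, so the second value largely follows from the first and is no separate evidence. Of the pairs sharing a number 43 of 45 lay over 0.1, and the lowest was -0.16. For 18 of 18 samples the best match in another group had their own number. The pairing itself comes from the block layout in the labels, and the fit with the replicate number as a block was an alternative. Most arrays also joined 2 samples of the same number, whose estimates then share the error of that array. Pairs sharing a number and an array had correlations of at least 0.475. Those sharing a number but no array ran from -0.16 to 0.577. A field block and shared arrays therefore cannot be told apart by these correlations.

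The code was tested on simulated data for canola kept to V8 against control over 39712 probes. It called 20% of probes set to a log2 change of 0.5, 86% at 1, 98% at 1.5 and 100% at 2, with 11 false calls. Of unchanged probes 5.01% had an unadjusted p under 0.05. The data were drawn from the fitted model, so such a share was built in. In the real data it ran from 1.99% for low nitrogen to 6.26% for canola kept against removed. The variance of log2 fold changes was 0.0296 against 0.0434 simulated for low nitrogen, and 0.0346 against 0.0289 for canola to V8. The spread assumed by the fit thus need not hold in each comparison. In a simulation of shade kept to V8 against control, a list lowered by 0.2 had a limma adjusted p of 1.34e-20 and 0 other lists passed. Its probes were drawn independently of each other, so it cannot show how often lists of correlated genes are called falsely. A spot counted as above background in a channel when at least 50% of its pixels exceeded background by the scanner's margin. A probe above background in no channel of a group has only a bound there. No fold is given for it, because the channel means such a bound would use carry array effects.

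Alternatives were no background subtraction, a normexp offset of 0, loess alone, quantile normalization of all channels, the probes brighter than the median probe, bad spots kept, limma on log ratios, limma's separate-channel fit, a plain mean of the 2 channels, the replicate block, a term for hybridisation day, the estimated correlation, and each biological sample left out in turn. Leaving out the dimmest array and weighting arrays by quality were added after the data were seen. The authors' value table was planned as an alternative and was not run, because its columns matched the scanner channels of other samples than their labels name.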

Results

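The series measured how the leaf transcriptome of maize at the V8 stage responded to a weed, to shade and to lack of nitrogen, and whether removing the weed or the shade at the V4 stage changed the outcome. The weed was canola sown at 7 kg of seed per hectare, the shade was a cloth blocking 40% of light, and low-nitrogen plots received 0 kg of added nitrogen per hectare against 236 kg elsewhere, on soil holding 44.5 kg. Each of the 6 groups held 3 biological samples, each a pool of leaf tips from 4 plants, and each sample was measured once with either dye. In a channel, between 32.5 and 76.7% of spots were above background (median 59.6%), against 4.26 to 12.8% of blank spots. The median ratio of spot signal to background ranged from 1.43 to 4.03. The group median of spots above background was 63% in control and lowest, at 51.2%, with shade removed at V4. The number of arrays limits the precision: the median SE of a log2 fold change was between 0.152 and 0.186 over the 9 comparisons. Every direction rests on the sample names attached to the scanner files, whereas most columns of the authors' value table matched channels of other samples.

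Canola kept to V8 against control asked what weed presence through V8 did to the maize leaf. Probes for cytosolic ribosomal proteins, which build the machinery of protein synthesis, fell as a group. Their median log2 fold change was -0.17 with 279 of 341 below 0, and camera of limma gave an adjusted p of 2.09e-14 (adjusted p = 0.283 with an estimated correlation). Their mean level relative to control was -0.17 ± 0.16 (SD, n = 3), below 0 in all 3 canola samples. The ranges overlapped, from -0.332 to -0.019 with canola and from -0.051 to 0.07 in control. Mitochondrial respiration probes, covering the electron transport chain and ATP synthase, fell with a median of -0.12 and 55 of 70 below 0 (limma camera, adjusted p = 9.08e-07; adjusted p = 0.156 with an estimated correlation). Circadian clock probes, which time daily gene activity, rose with a median of 0.092 and 23 of 30 above 0 (limma camera, adjusted p = 0.000269; adjusted p = 0.41 with an estimated correlation).

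Among the ribosomal members, 60S L1 (MZ00037676) had a log2 fold change of -0.80 ± 0.20 (SE, n = 3 per group), 60S L31 (MZ00035747) -0.78 ± 0.20 and 40S S7 (MZ00042938) -0.72 ± 0.18. Of the 386 measured ribosomal probes, 0 passed when adjusted over the list alone. Of 77 respiration probes 2 passed when adjusted over the list alone, both lower. These were cytochrome c oxidase subunit VIa (MZ00041545) at -0.46 ± 0.11 and the 29 kDa subunit of complex I (MZ00026640) at -0.50 ± 0.13, each with a limma adjusted p of 0.0466 over the list. In the clock list, a gigantea-like probe (MZ00013976) had 0.72 ± 0.24 and was higher in 2 of 3 samples. In the same list LHY (MZ00001133), a morning-phased transcription factor, had 0.62 ± 0.21, and pseudo-response regulator 73 (MZ00015603) had 0.58 ± 0.25. Of 80 nitrogen assimilation probes 1 passed when adjusted over the list alone: the root isozyme 2 of glutamine synthetase (MZ00016322), which fixes ammonium, at -0.80 ± 0.19 (limma, adjusted p = 0.0392 over the list). The leading probes outside the lists were an unnamed protein (MZ00019752) at 0.97, the unnamed MZ00028951 at 1.42 ± 0.22 (limma, adjusted p = 0.0952 for each) and an inositol polyphosphate-5-phosphatase-like probe (MZ00004787) at 1.29 ± 0.25. The 2 protein phosphatase 2C probes (MZ00027477 and MZ00047853) had 0.74 ± 0.14 and 0.66 ± 0.13. A ribulose-5-phosphate 3-epimerase probe (MZ00024241), for an enzyme of the Calvin and pentose phosphate cycles, stood at 0.68. Lower values were seen for ketol-acid reductoisomerase (MZ00013938), an enzyme of valine and isoleucine synthesis, at -0.65 ± 0.13 and a MADS-box factor (MZ00040643) at -0.67. They were also seen for a proline-rich APG protein (MZ00056661) at -0.71 and an unnamed probe (MZ00018234) at -1.55 ± 0.33. Apart from the gigantea-like probe and MZ00028951, whose samples were not counted here, these single probes were shifted the same way in 3 of 3 samples.

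Single probes past the threshold with canola kept to V8 numbered 0 by limma, while 2578 had an unadjusted p under 0.05. By chance 2170 would in each of the 9 comparisons, a number that 3 of them exceeded: this one, canola kept against removed, and canola against shade. The log-ratio fit gave 1 and the separate-channel fit, which treats both labellings of a sample as independent, gave 221. In the log-ratio fit, too, the 2 arrays of a sample count as independent. Without control 3 or without shade to V8 replicate 1 limma gave 2, and 6 lists passed without control 1 or 3. The ribosomal and clock calls were lost without control replicate 2, which shared arrays with canola to V8 replicates 1 and 2. The medians were then -0.065 (limma camera, adjusted p = 0.055) and 0.032 (adjusted p = 0.835). With the plain mean of 2 channels the clock call was lost too (adjusted p = 0.185). With the replicate block, antioxidant enzymes (adjusted p = 0.0383, against 0.271) and chloroplast translation (adjusted p = 0.0104, against 0.104) passed too, both lower.

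**Figure D1:**
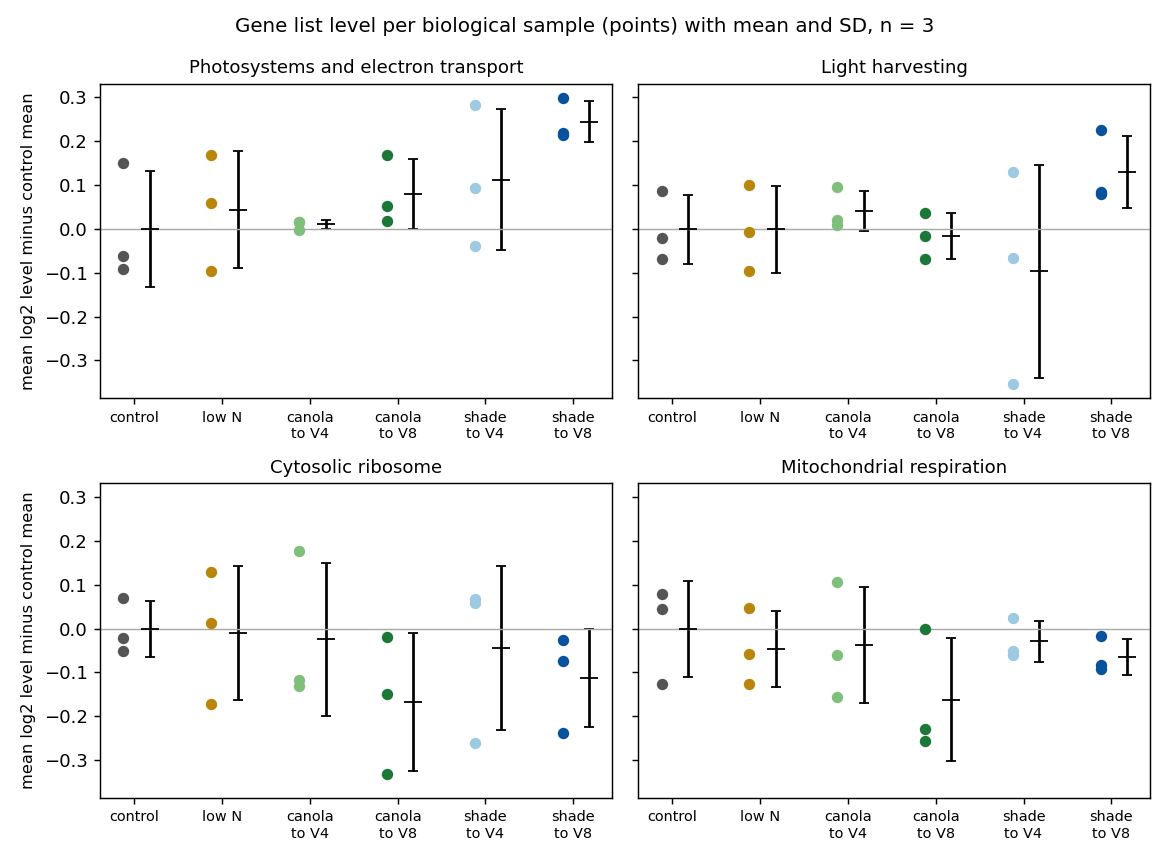
Mean log2 level of 4 gene lists in each biological sample, relative to the control mean (vertical axis), for the 6 groups (horizontal axis); points are samples and bars show the mean and SD (n = 3). Photosystem probes lay between 0.21 and 0.30 in the 3 samples shaded to V8, and ribosomal probes between -0.33 and -0.019 in the 3 samples with canola to V8.

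Shade kept to V8 against control asked what lasting shade did. Photosystem and electron transport probes, which encode the light reactions of photosynthesis, rose with a median log2 fold change of 0.21 and 87 of 111 above 0 (limma camera, adjusted p = 8.14e-13; adjusted p = 0.163 with an estimated correlation). Their level was 0.24 ± 0.05 above control (SD, n = 3), above 0 in all 3 samples. Light-harvesting probes rose with a median of 0.17 and 24 of 33 above 0 (limma camera, adjusted p = 0.00178; adjusted p = 0.416 with an estimated correlation). Chlorophyll and carotenoid synthesis probes rose with a median of 0.085 and 25 of 37 above 0 (adjusted p = 0.00109; adjusted p = 0.163 with an estimated correlation). Phosphate and sulphate probes, mostly transporters and phosphatases, rose with a median of 0.12 and 32 of 48 above 0 (limma camera, adjusted p = 0.000756; adjusted p = 0.393 with an estimated correlation). Ribosomal probes fell with a median of -0.11 and 255 of 341 below 0 (adjusted p = 5.49e-06; adjusted p = 0.438 with an estimated correlation). Respiration probes fell with a median of -0.058 and 44 of 70 below 0 (adjusted p = 0.00304; adjusted p = 0.393 with an estimated correlation).

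Within the light-harvesting list the members split: of 60 measured probes, 2 were higher and 3 lower when adjusted over the list alone. The lower ones were early light-induced proteins, which protect the photosynthetic membrane under strong light. They were MZ00019578 at -2.12 (limma, adjusted p = 0.00266 over the list and 0.25 over all probes), MZ00041757 at -1.44 ± 0.29 and MZ00036421 at -0.79 ± 0.18. The higher ones were chlorophyll a/b-binding protein 2 (MZ00013603), an antenna protein, at 0.73 ± 0.21 and photosystem I subunit III (MZ00024041) at 0.46 ± 0.14. Photosystem members included the 10.8 kD photosystem I protein (MZ00042853) at 0.52 ± 0.13 and the photosystem II 44 kDa reaction centre protein (MZ00034845) at 1.05 ± 0.31. In pigment synthesis, protochlorophyllide oxidoreductase (MZ00034323), which catalyses the light-driven step towards chlorophyll, had 1.13 ± 0.39. In the phosphate and sulphate list 2 of 49 probes were higher when adjusted over the list alone, sulfate transporter ST1 (MZ00019403) at 0.80 ± 0.19 and purple acid phosphatase (MZ00016369) at 0.63 ± 0.15 (limma, adjusted p = 0.0114 over the list for each). In the respiration list, alternative oxidase 1a (MZ00018270) had -0.41 ± 0.14 and mitochondrial uncoupling protein 4 (MZ00017043) -0.56 ± 0.15. Every probe named here was shifted the same way in 3 of 3 samples.

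The leading single probes under lasting shade were a benzothiadiazole-induced salicylic acid carboxyl methyltransferase (MZ00032043), which makes methyl salicylate, at 1.49 ± 0.22 (limma, adjusted p = 0.103), and an unnamed probe (MZ00057050) at 1.84 ± 0.31 (adjusted p = 0.156). Lower values were seen for acetohydroxyacid isomeroreductase (MZ00021664), another annotation of ketol-acid reductoisomerase, at -1.19 ± 0.19 (adjusted p = 0.133; above background in 1 of 6 channels under shade), and an ethylene-induced esterase (MZ00032401) at -0.98 ± 0.18. They were also seen for 2 chitinases (MZ00014842 and MZ00014841), which degrade chitin in defence, at -0.77 ± 0.14 and -0.72 ± 0.15, and a MADS-domain factor (MZ00016529) at -0.81 ± 0.16. The esterase passed in the ethylene list (limma, adjusted p = 0.00355 over the list alone) and the chitinases in the defence list (0.00987 and 0.0204). A gibberellin 2-oxidase (MZ00044694), which inactivates gibberellin, passed over its hormone list alone at -0.75 ± 0.15 (limma, adjusted p = 0.00489). These probes were shifted the same way in 3 of 3 samples. Past the threshold over all probes were 0 by limma, with 1775 at an unadjusted p under 0.05. The log-ratio fit gave 11 and the separate-channel fit 114, and without shade to V8 replicate 2 limma gave 11. Without shade to V8 replicate 3 the phosphate and sulphate median was 0.031 (limma camera, adjusted p = 0.422) and that of respiration -0.074 (0.0527), while without control replicate 3 respiration stood at -0.03 (0.332). With the plain mean of 2 channels the respiration median turned to 0.056 (adjusted p = 0.649). With bad spots kept the light-harvesting median was 0.078 (adjusted p = 0.0527). With the replicate block the C4 cycle list also passed, higher (adjusted p = 0.011, against 0.266).

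**Figure D2:**
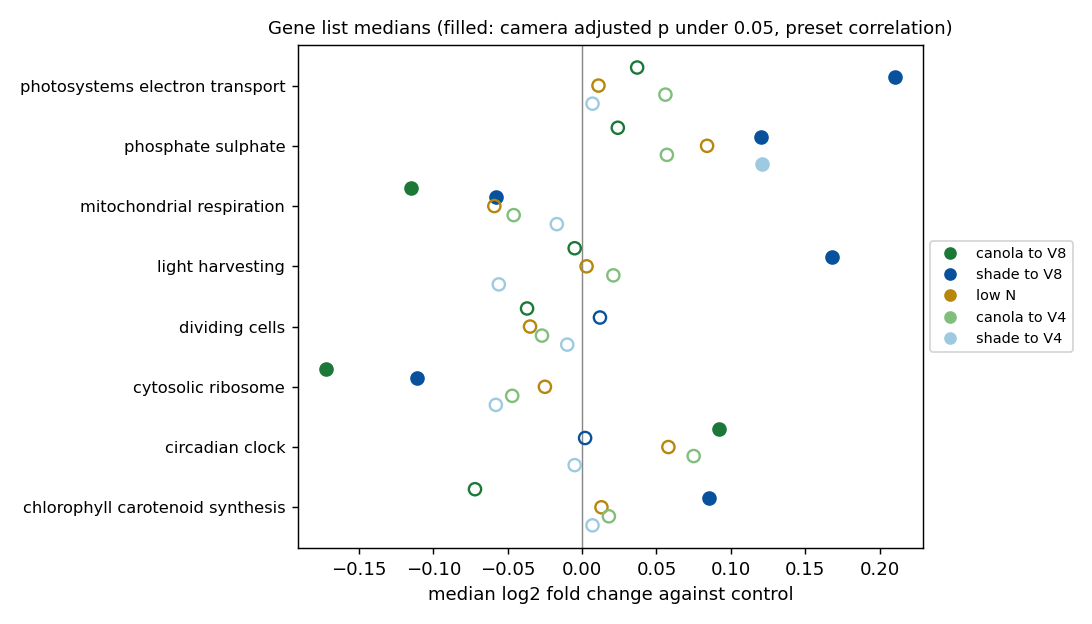
Median log2 fold change against control (horizontal axis) of 8 gene lists in the 5 stress comparisons; filled points passed camera of limma at an adjusted p of 0.05 with the preset correlation and open points did not. The photosystem list stood at 0.21 with shade to V8 and the ribosomal list at -0.17 with canola to V8.

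Low nitrogen against control asked what nitrogen shortage did. Nitrogen assimilation probes, for enzymes and transporters that take up and fix nitrate and ammonium, lay around 0, with 36 of 71 above it and a limma camera adjusted p of 0.923. The lowest adjusted p over the lists, 0.0554, was shared by the circadian clock (median 0.058), jasmonate and lipoxygenase (0.069) and phosphate and sulphate (0.077) lists. With the replicate block these 3 lists passed, each at an adjusted p of 0.0349, so that 3 lists against 0 were called; leaving out shade removed at V4 replicate 3 gave 3 lists too. Leading single probes included spermidine synthase 1 (MZ00043285), a polyamine enzyme, at 0.60 ± 0.15, a guanylate-binding protein (MZ00052046) at 0.75 ± 0.18 and an EREBP-like probe (MZ00018541), of the ethylene-response factor family, at 0.69 ± 0.17. Lower values were seen for a peroxidase (MZ00026737) at -0.82 ± 0.22 and a potassium channel (MZ00051358) at -0.68 ± 0.20. An unnamed probe (MZ00013977), above background in 3 low-nitrogen channels and 0 control channels, is given no fold. Each was shifted the same way in 3 of 3 samples with a limma adjusted p of 1. Of all probes 0 passed by limma, 863 had an unadjusted p under 0.05, and the log-ratio and separate-channel fits gave 0 each.

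Canola removed at V4 against control asked whether early weed presence left a trace at V8. The leading probes were ribulose-5-phosphate 3-epimerase (MZ00024241) at 0.82 ± 0.15, a phosphate/phosphoenolpyruvate translocator (MZ00038961), which exchanges these compounds across the plastid envelope, at 0.95. Next were the H isozyme of glucan phosphorylase (MZ00023027), which breaks down glucans, at 0.64 ± 0.15 and malate dehydrogenase (MZ00043237) at 0.58 ± 0.14. Lower values were seen for a pollen germination related PGPD14 probe (MZ00031569) at -0.69 ± 0.18 and an RNA helicase (MZ00028834) at -0.66 ± 0.17. Each was shifted the same way in 3 of 3 samples with a limma adjusted p of 1. Of all probes 0 passed by limma, with 1231 at an unadjusted p under 0.05. The log-ratio fit gave 0 and the separate-channel fit 1. Of the lists, 0 passed limma camera, the lowest adjusted p being that of the circadian clock, 0.101 with a median of 0.075. Among aquaporins, the water channels, 12 of 18 were above 0 (median 0.13, adjusted p = 0.164). Without canola removed at V4 replicate 3, 4 lists passed, and without control replicate 3, 3 did.

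Shade removed at V4 against control asked the same of early shade. Phosphate and sulphate probes rose with a median of 0.12 and 38 of 48 above 0 (limma camera, adjusted p = 0.000788; adjusted p = 0.86 with an estimated correlation), including sulfate transporter ST1 (MZ00019403) at 0.72 ± 0.22 and a glycerol-3-phosphate transporter (MZ00027556) at 0.73 ± 0.26. Without shade removed at V4 replicate 1 their median was 0.044 (adjusted p = 0.28). Among single probes, the unnamed MZ00057050 had 1.70 ± 0.36 and monodehydroascorbate reductase (MZ00041790), which regenerates ascorbate, 0.95 ± 0.25. Lower values were seen for 1,3-beta-glucanase (MZ00030174), a cell wall and defence hydrolase, at -1.01 ± 0.22 and the MADS-domain factor MZ00016529 at -0.89 ± 0.18. The dehydration-responsive RD22 (MZ00057294) had -1.02 and passed over the abscisic acid list alone (limma, adjusted p = 0.026). Acetohydroxyacid isomeroreductase (MZ00021664) was above background in 0 of the channels of this group and in 6 of the control channels, and is given no fold. These probes were shifted the same way in 3 of 3 samples. Over all probes 0 passed by limma, each named one having an adjusted p of 1, with 1173 at an unadjusted p under 0.05. The log-ratio fit gave 0 and the separate-channel fit 1. Lists past the threshold numbered 4 without control replicate 2 or without shade removed at V4 replicate 2.

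Canola kept to V8 against canola removed at V4 asked what weed presence from V4 on added. Ribosomal probes fell with a median of -0.14 and 260 of 341 below 0 (limma camera, adjusted p = 1.27e-09; adjusted p = 0.558 with an estimated correlation). Respiration probes fell with a median of -0.10 and 50 of 70 below 0 (adjusted p = 0.000228; adjusted p = 0.558 with an estimated correlation). Ribosomal L21 (MZ00023795) at -0.93 ± 0.17 and L7 (MZ00043110) at -0.62 ± 0.13 passed when adjusted over the list alone (limma, adjusted p = 0.014 and 0.0204). Among single probes, the unnamed MZ00028951 had 1.52 ± 0.22 (limma, adjusted p = 0.0708). Photosystem I PsaB (MZ00034839), a reaction centre protein encoded in the chloroplast, had 1.08 ± 0.17 (limma, adjusted p = 0.119 over all probes and 0.000764 over its list alone), and was saturated in 2 channels with canola kept to V8, so the size of its change is uncertain. Glutamine synthetase probes went both ways, with 0.74 ± 0.14 for MZ00044001 and -0.88 ± 0.19 for the root isozyme 2 (MZ00016322; limma, adjusted p = 0.00546 and 0.00771 over the nitrogen list alone). A beta-1,3-glucanase probe (MZ00037292) had -0.82 ± 0.16 (limma, adjusted p = 0.0199 over the defence list alone). The defence list as a whole had a median of -0.056 with 152 of 233 below 0 (limma camera, adjusted p = 0.0504). All of these probes were shifted the same way in 3 of 3 samples. Over all probes 0 passed by limma, with 2715 at an unadjusted p under 0.05. The log-ratio fit gave 2 and the separate-channel fit 168. Without canola kept to V8 replicate 3, or without shade kept to V8 replicate 1, limma gave 1.

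Shade kept to V8 against shade removed at V4 asked what shade from V4 on added. Light-harvesting probes rose with a median of 0.33 and 24 of 33 above 0 (limma camera, adjusted p = 8.8e-08; adjusted p = 0.255 with an estimated correlation). These 33 were the probes with complete values among 60 measured. Among the samples with shade removed, replicate 2 stood apart, with a light-harvesting level relative to control of -0.35 against -0.067 and 0.13 in replicates 1 and 3. In it epidermis markers stood at 0.45 against -0.12 and -0.24, and vascular markers at 0.23 against -0.041 and -0.045. Of its 2 channels 1 lay on the dimmest array, with 50.5% of spots above background. The other channel of that array held shade kept to V8 replicate 2, with 32.5%. Without shade removed at V4 replicate 2 the light-harvesting median was 0.20 (adjusted p = 0.00332). Photosystem probes rose with a median of 0.15 and 75 of 111 above 0 (adjusted p = 5.57e-07; adjusted p = 0.305 with an estimated correlation), and chlorophyll and carotenoid synthesis probes with a median of 0.13 and 25 of 37 above 0 (adjusted p = 0.0047; adjusted p = 0.255 with an estimated correlation). Ribosomal probes fell with a median of -0.058 and 222 of 341 below 0 (adjusted p = 0.0354; adjusted p = 0.821 with an estimated correlation). When adjusted over the list alone, 5 light-harvesting probes were higher and 1 lower. A type 1 antenna protein (MZ00035077) had 0.74 ± 0.15, with 3 channels saturated under shade to V8 and 1 with shade removed, so the size of its change is uncertain. The type III antenna protein of photosystem II (MZ00036529) had 0.71 ± 0.17, and the early light-induced protein MZ00019578 -1.28 ± 0.37, lower in 2 of 3 samples. Uroporphyrinogen decarboxylase (MZ00026065), an early enzyme of chlorophyll synthesis, had 0.93 ± 0.19 (limma, adjusted p = 0.00413 over its list alone). The flavonoid enzyme naringenin 3-dioxygenase (MZ00044256), above background in 0 of the channels with shade removed at V4, was higher, with no fold given (limma, adjusted p = 0.265 over all probes and 0.00414 over its list alone). Values were -1.08 ± 0.25 for the proline-forming pyrroline-5-carboxylate synthetase (MZ00025596) and -0.98 ± 0.22 for DRE binding factor 2 (MZ00024362), a drought and cold regulator.

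Over all probes 0 passed by limma between shade kept and shade removed, with 1857 at an unadjusted p under 0.05. The log-ratio fit gave 0 and the separate-channel fit 33. With the replicate block 2 passed, the RISBZ5 transcription factor (MZ00026870) at 1.03 ± 0.15 (limma, adjusted p = 0.0424) and an unannotated probe (MZ00041654) at 1.19 ± 0.15 (0.0204). The block called 8 lists against 4, adding the C4 cycle, jasmonate, senescence and vascular lists, each at an adjusted p of 0.0381. The ribosomal call was lost with any of 8 samples left out: control 1, low nitrogen 2, canola removed at V4 3, canola to V8 3, shade removed at V4 2 and 3, and shade to V8 1 and 3, with an adjusted p of up to 0.559. It was also lost with an offset of 0, quantile normalization, the plain mean, quality weights, or without the dimmest array (adjusted p up to 0.424). Without shade removed at V4 replicate 2 the pigment synthesis median was 0.14 (adjusted p = 0.0907), and that call was also lost with an offset of 0 (0.0997) and without the dimmest array (0.0694). Without shade to V8 replicate 3, 4 probes passed. Lists past the threshold then numbered 9 without shade removed at V4 replicate 1 and 2 without its replicate 2.

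Canola kept to V8 against shade kept to V8 asked whether weed and shade acted alike. Acetohydroxyacid isomeroreductase (MZ00021664), of branched-chain amino acid synthesis, was higher with canola by 1.72 ± 0.23 (limma, adjusted p = 0.0219), at 8.89 ± 0.58 against 7.17 ± 0.45 (SD, n = 3 each). It was above background in 6 of 6 channels with canola but in 1 of 6 with shade, so the size of the change is uncertain. Of the other probes for this enzyme, MZ00013938 had -0.68 ± 0.16 (limma, adjusted p = 0.295), MZ00041711 0.45, and the remaining 5 lay between -0.22 (MZ00014876) and 0.16 (MZ00014017). The unnamed MZ00028951 was higher by 1.83 ± 0.26 (limma, adjusted p = 0.035), at 11.64 ± 0.55 against 10.02 ± 0.45. Both probes called were higher in 3 of 3 samples. Chlorophyll and carotenoid synthesis probes were lower with canola, with a median of -0.19 and 28 of 37 below 0 (limma camera, adjusted p = 0.00223; adjusted p = 0.258 with an estimated correlation). Photosystem probes were lower too, at -0.15 with 71 of 111 below 0 (adjusted p = 0.00475; adjusted p = 0.61 with an estimated correlation). Ribosomal probes were lower at -0.079 with 239 of 341 below 0, and clock probes higher at 0.17 with 21 of 30 above 0 (adjusted p = 0.0345 each; adjusted p = 0.61 with an estimated correlation). The mean clock levels relative to control nevertheless lay close together, at 0.13 ± 0.12 with canola and 0.12 ± 0.04 with shade (SD, n = 3 each). Dividing-cell markers, histones and replication proteins, were lower at -0.066 with 136 of 223 below 0 (adjusted p = 0.0347; adjusted p = 0.483 with an estimated correlation).

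Just short of the threshold between canola and shade were RD22 (MZ00057294) at 1.49 ± 0.23 and the salicylic acid methyltransferase (MZ00032043) at -1.69 ± 0.26, each with a limma adjusted p of 0.0516. They were followed by steroleosin (MZ00005314), an oil body protein, at 1.25 ± 0.20 (0.0659), citrate synthase (MZ00024247), of the citric acid cycle, at -1.16 ± 0.19 (0.0691), and the phosphatase-like MZ00004787 at 1.81 ± 0.30 (0.0738). Chloroplast glutamine synthetase GS2 (MZ00014550) had -0.94 ± 0.21 (limma, adjusted p = 0.0201 over its list alone). In pigment synthesis uroporphyrinogen decarboxylase (MZ00026065) had -0.78 ± 0.22. In the photosystem list plastocyanin (MZ00039373) had -0.51 ± 0.16 and photosystem I subunit N (MZ00035161) 0.91 ± 0.22. Among dividing-cell markers, histone H3 (MZ00057261) had -0.80 ± 0.22.

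The replicate block called 8 probes against 2 between canola and shade, 5 higher and 3 lower with canola. They included MZ00021664, RD22 (MZ00057294) at 1.62 ± 0.23 and a lipid transfer protein (MZ00026029) at 1.44 ± 0.19, each with a limma adjusted p of 0.0248. MZ00028951 and the phosphatase-like MZ00004787, at 1.91 ± 0.28, were higher too, and the unnamed MZ00057050 was lower at -2.41 (limma, adjusted p = 0.0335 each). Also lower were citrate synthase (MZ00024247) at -1.18 ± 0.19 (limma, adjusted p = 0.0367) and the beta subunit of pyruvate dehydrogenase (MZ00014231, 0.0367), which feeds the citric acid cycle. It called 12 lists against 5, losing the clock (adjusted p = 0.18) and dividing-cell (0.128) lists. It added the C4 cycle (0.0348), Calvin cycle (0.00776), light harvesting (0.0184), jasmonate (0.0294), and antioxidant (0.0423) lists, and also the chloroplast translation (0.00309), phosphate and sulphate (0.00414), respiration (0.0184) and epidermis (0.0153) lists. At an unadjusted p under 0.05 stood 2668 probes. The log-ratio fit called 4 and the separate-channel fit 144. The call of MZ00021664 was lost without control 1 or 2, low nitrogen 1, canola to V8 1 or 2, or shade to V8 1 or 3 (adjusted p up to 0.21), and with an offset of 0 (0.131) or the plain mean (0.557). That of MZ00028951 was lost without control 1, 2 or 3, low nitrogen 1 or 3, canola removed at V4 1 or 3, canola to V8 1, 2 or 3, shade removed at V4 3 or shade to V8 3 (adjusted p up to 0.264), and without background subtraction (0.0657), with an offset of 0 (0.131) or the plain mean (0.637). The clock, ribosomal and dividing-cell calls were each lost with 6 samples left out in turn, control 2 and 3, canola to V8 1 and shade to V8 2 among them for every list. The others were canola removed at V4 3 for clock and ribosome, shade to V8 1 for clock and dividing cells, low nitrogen 2 for ribosome and canola to V8 3 for dividing cells. Their adjusted p then reached 0.524, 0.878 and 0.292. All 3 were also lost with an offset of 0 or the plain mean, clock and dividing cells with quality weights, and clock with quantile normalization or among brighter probes. With the plain mean the clock median turned to -0.014 (adjusted p = 0.871). The photosystem call was lost without shade to V8 1 (adjusted p = 0.0778) and with the log-ratio fit (0.104), which also ended the pigment synthesis call (0.0676). Without shade to V8 2 limma called 12 probes. Lists numbered 2 without canola to V8 1 and 8 without canola removed at V4 2 or shade removed at V4 1.

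Canola kept to V8 against low nitrogen asked whether the weed acted like nitrogen shortage. The unnamed MZ00028951 was higher with canola by 1.94 ± 0.26 (limma, adjusted p = 0.0241), at 11.64 ± 0.55 against 9.80 ± 0.27 (SD, n = 3 each) and in 3 of 3 samples. Ribosomal probes were lower with a median of -0.15 and 256 of 341 below 0 (limma camera, adjusted p = 2.4e-10; adjusted p = 0.579 with an estimated correlation). Respiration probes were lower with a median of -0.10 and 48 of 70 below 0 (adjusted p = 0.00621; adjusted p = 0.579 with an estimated correlation). Members were 60S L30 (MZ00023944) at -0.94 ± 0.28, L21 (MZ00023795) at -0.75 ± 0.20 and complex I 29 kDa (MZ00026640) at -0.45. Elongation factor 1 alpha (MZ00037991), which delivers aminoacyl-tRNA to the ribosome, had -0.89 ± 0.20, and cytosolic glyceraldehyde 3-phosphate dehydrogenase (MZ00057421) of glycolysis -0.66 ± 0.16. Beta-1,3-glucanase (MZ00037292) had -0.91 ± 0.19 (limma, adjusted p = 0.0398 over the defence list alone). Probes at an unadjusted p under 0.05 numbered 1672. The log-ratio fit called 0 and the separate-channel fit 7. The replicate block called 6 lists against 2, adding chlorophyll synthesis (adjusted p = 0.0247), chloroplast translation (0.0389), phosphate and sulphate (0.0417) and epidermis (0.0188). The call of MZ00028951 was lost without control 3, low nitrogen 1 or 3, canola removed at V4 1 or 3, canola to V8 1 or 3, shade removed at V4 2 or 3, or shade to V8 2 or 3 (adjusted p up to 0.54). It was also lost without background subtraction (0.0521), with an offset of 0 (0.101), log ratios (0.0556) or the plain mean (1). The respiration call was lost without low nitrogen 1, canola removed at V4 1 or canola to V8 1 (up to 0.176), and with log ratios (0.103). Without control 3, canola removed at V4 2, canola to V8 3 or shade to V8 2, 4 lists passed.

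**Figure D3:**
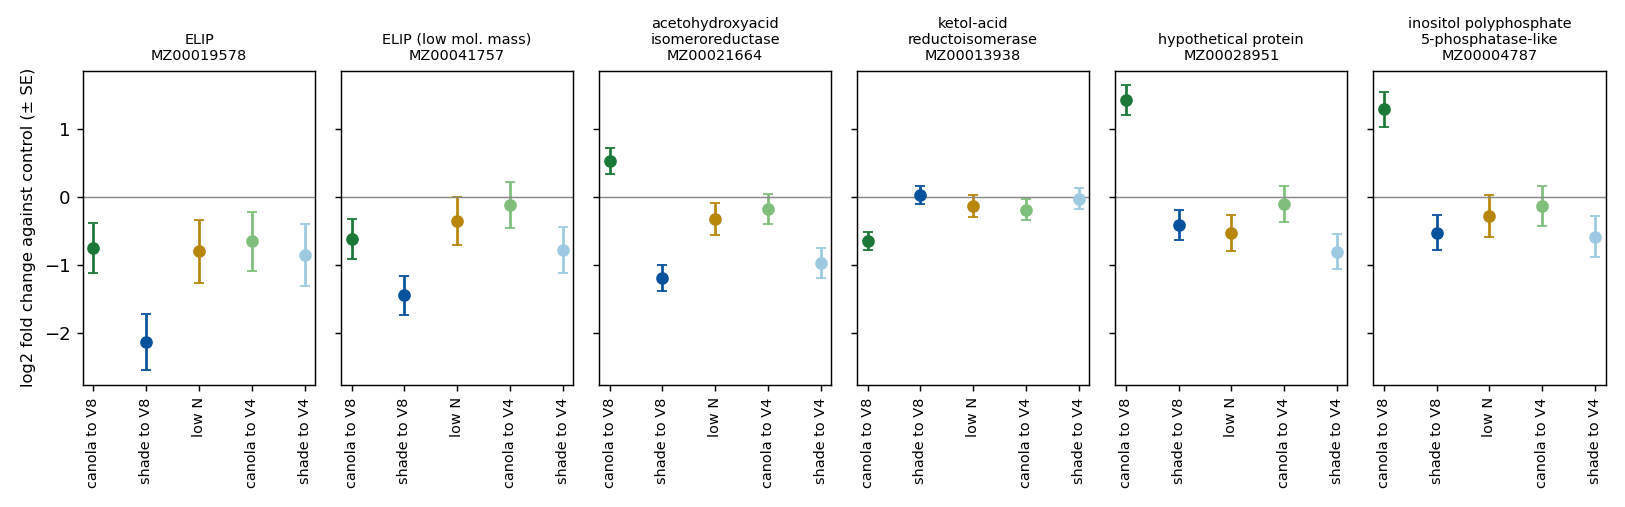
Log2 fold change against control (vertical axis) of 6 probes in the 5 stress comparisons, with bars for the SE (n = 3 per group). MZ00021664 was above background in 0 channels with shade removed at V4, so the size of its plotted change there is uncertain. MZ00028951 stood at 1.42 with canola to V8 and at or below -0.10 in the other comparisons, and the early light-induced protein MZ00019578 at -2.12 with shade to V8.

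Across the comparisons against control, probes past the threshold in any pair of them numbered 0 by limma. The log2 fold changes of canola to V8 and shade to V8 correlated at 0.195 over 39712 probes, which are not independent replicates, against 0.274 in simulated unchanged groups sharing the controls, and their covariance was 0.00623 against 0.00796. Low nitrogen and canola removed at V4 correlated most, at 0.695 against 0.652 simulated, with a covariance of 0.0216 against 0.027. In all 10 pairs the observed covariance lay below the simulated one, which leaves out the pairing by replicate number. With that pairing the chance covariance was 0.00595 for canola to V8 and shade to V8, below the observed value, and 0.0102 for shade to V8 and canola removed at V4, where 0.0102 was observed. In the other 8 pairs the observed covariance lay below that chance value too. The 3 control samples are too few to split, and part of each correlation may come from them. At an unadjusted p under 0.05 in both comparisons of a pair, the number of probes shifted the same way lay above the simulated number in 3 of 10 pairs and below it in 7. It was 203 against 111 for canola to V8 and shade to V8, and 188 against 396 for low nitrogen and shade removed at V4.

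The remaining lists passed in 0 comparisons with limma camera. Their lowest adjusted p was 0.124 for nitrogen assimilation (shade removed at V4, median 0.064), 0.0643 for the Calvin cycle (canola against shade, -0.16), 0.266 for the C4 cycle (shade to V8, 0.075). It was 0.251 for phytochrome and shade signalling (canola kept against removed, 0.059) and 0.617 for auxin (canola kept against removed, 0.023). For gibberellin with brassinosteroid and cytokinin it was 0.48 (canola against shade, -0.071), for ethylene 0.692 (shade to V8, -0.023). For abscisic acid with dehydrins it was 0.196 (shade kept against removed, -0.054) and for phenylpropanoids 0.479 (shade kept against removed, -0.044). Glutathione transferases reached 0.48 (canola against shade, 0.025), sucrose and starch 0.343 (canola against shade, -0.043), and senescence and proteolysis 0.0646 (shade kept against removed, -0.059). Chloroplast translation reached 0.0672 (canola against shade, -0.094), heat shock and chaperones 0.303 (canola against shade, 0.031) and cell wall and growth 0.175 (canola against shade, -0.043). Of the lists for other cell types, 0 passed in a comparison against control; dividing cells came nearest, at -0.037 with canola to V8 (adjusted p = 0.0619). Epidermis and cuticle reached 0.173 (canola against low nitrogen, 0.085), vascular cells 0.0951 (shade kept against removed, -0.024), pollen and seed 0.26 (canola against shade, -0.048) and root 0.444 (low nitrogen, -0.071).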

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

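The test of dividing cells and the leaving out of samples from the interaction test were chosen only after the results they bear on were seen. The interaction test itself was not among the comparisons fixed before the data were examined. The tests of brightness, of a single deviating sample, of hybridisation day and of the splits were planned. The change from a stress removed at V4 to the same stress kept to V8 differed between canola and shade for 5 gene lists by an interaction test with limma camera. The difference, canola minus shade, had a median of -0.27 for light harvesting (28 of 33 probes below 0, adjusted p = 1.33e-05; adjusted p = 0.322 with an estimated correlation) and of -0.22 for photosystems (78 of 111 below 0, adjusted p = 0.00799; 0.696 with an estimated correlation), where the mean was only -0.033. It was -0.20 for chlorophyll and carotenoid synthesis (26 of 37 below 0, adjusted p = 0.000598; 0.208 with an estimated correlation), 0.12 for senescence and proteolysis (94 of 136 above 0, adjusted p = 0.00796; 0.435 with an estimated correlation) and -0.093 for ribosomal proteins (220 of 341 below 0, adjusted p = 0.0113; 0.716 with an estimated correlation). With each of the 18 samples left out in turn, 0 ended the light-harvesting and chlorophyll calls, 3 that of photosystems, 4 that of senescence and 7 that of ribosomal proteins (limma camera, adjusted p up to 0.0108, 0.0123, 0.407, 0.169 and 0.414). The light-harvesting test covered only the 33 probes with complete values among 60 measured. Shade removed at V4 replicate 2, measured in part on the dimmest array, stood apart. Its light harvesting was at -0.35, epidermis markers at 0.45 and vascular markers at 0.23 relative to control. Without it the light-harvesting median was -0.23 (adjusted p = 0.0108), and photosystems did not pass (median -0.17, mean 0.035, adjusted p = 0.407). The replicate block added the C4 cycle (0.0113) and epidermis (0.0288) lists. Single probes past the threshold for this difference numbered 0 by limma, with 2472 at an unadjusted p under 0.05.

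Control oligonucleotides, which no comparison used, gave signal on these arrays. The class named alien was above background in a median over channels of 44% of spots (12 to 92.4%). The class whose names start with H stood at 47.9% (16.7 to 94.4%) and the remaining control oligonucleotides at 65.9% (51 to 77.6%). The medians were 8.39% for blank spots and 0.521% for buffer spots. Whether spike-in RNA was added for them is not given in the sources used here.

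The fall of ribosomal probes with canola kept to V8 was weighed against 3 technical explanations and 1 of tissue makeup. A trend with brightness was argued against, since the list's median lay at percentile 0 of 10000 lists matched on brightness, whose medians ran from -0.051 to 0.027. With a term for hybridisation day the median was -0.18. This cannot decide on hybridisation day, because each array had a single day and the fit already took up array effects. Such a term could therefore hardly move the median. Fewer dividing cells would need their markers to fall alike, and these had a median of -0.037 (bootstrap interval over probes -0.074 to -0.02). That interval resampled probes of the same samples and leaves out the spread between samples, so it cannot decide this explanation. A single deviating sample stays open as a candidate explanation: without control replicate 2 the median was -0.065 (limma camera, adjusted p = 0.055). That value cannot decide it, because leaving out this sample also left canola to V8 replicates 1 and 2 sharing no array with a control. The list's levels in the control samples ran from -0.051 to 0.07. Hybridisation day and an effect of the weed stay open as well.

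For the rise of photosystem probes with shade kept to V8, the tests argued against a trend with brightness and a single deviating sample. The median lay at percentile 100 of brightness-matched lists (-0.077 to 0.081). It was 0.23 with a term for hybridisation day, which cannot decide on that explanation for the reason given for the ribosomal probes. The value nearest to 0 with 1 of the 6 samples left out was 0.13, with a limma camera adjusted p of at most 3.78e-05. A response to shade is therefore a hypothesis that these tests leave standing, although the call was lost with an estimated correlation (adjusted p = 0.163).

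Of 6 samples in a comparison, 10 splits into 3 and 3 exist, too few for a share under 0.05. Counts of probes, for the real split and the highest of the other splits, were 0 and 18 for canola to V8 against control, 0 and 5 for shade to V8, 0 and 1 for low nitrogen, and 0 and 0 for both stresses removed at V4 and for canola kept against removed. They were 0 and 2 for shade kept against removed, 2 and 0 for canola against shade, and 1 and 0 for canola against low nitrogen. In the first 7 of these comparisons the real split called 0 probes, so all 10 splits gave as many by necessity and the tally says nothing there. In each of the last 2 comparisons no other split gave as many probes as the real one. Counts of lists were 3 and 7 for canola to V8, 6 and 6 for shade to V8, 0 and 5 for low nitrogen, 0 and 6 for canola removed, and 1 and 13 for shade removed. They were 2 and 6 for canola kept against removed, 4 and 7 for shade kept against removed, 5 and 5 for canola against shade, and 2 and 6 for canola against low nitrogen. Splits with at least as many lists, the real split included, numbered 9, 2, 10, 10, 9, 7, 4, 2 and 4 in that order. Each 10 follows by necessity from 0 lists in the real split. Among splits that part all pairs of replicate numbers, the highest other count of probes was 0 for canola to V8, 5 for shade to V8 and 0 elsewhere. The highest count of lists was 7, 5, 5, 2, 6, 6, 7, 3 and 2 in the same order. The split with 18 probes set control replicates 1 and 2 and canola replicate 2 against the rest. It keeps together both samples of replicate number 2 and both of number 3, pairs whose deviations correlated at 0.577 and 0.35, and parts those of number 1, at -0.16. The samples of number 2 also shared an array, whereas those of number 1 and those of number 3 did not. This points to a structure of the samples that in part follows the replicate numbers. Shared arrays cannot be told apart here from another cause tied to the numbers. With the replicate block the real split called 0 probes by limma, with 3213 at an unadjusted p under 0.05.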

How the results depend on the processing

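The alternatives without the dimmest array and with array quality weights, and the use of the normalization, background and fit alternatives on lists, were chosen only after the data were seen; the others were planned. Of 179 results for named probes 178 kept their direction in every alternative that gave them a value, as did 21 of 23 for lists, on which the separate-channel fit was not run. With the plain mean of 2 channels, LHY (MZ00036336) between canola and shade was -0.039 against 0.79. In that fit, which leaves array effects in the values, the respiration median with shade to V8 was 0.056 and the clock median between canola and shade was -0.014. The median signal was 2.13 times background, and among brighter probes 0 passed by limma in each of the 5 comparisons against control. The overlap between comparisons was 8 with the separate-channel fit and 0 in the other fits. The authors' value table was not run. Except where stated, the cause of a change was not tested.

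Counts of probes past the threshold by limma that moved by over 1.5 times were as follows, against 0 unless stated; 1 smaller move, to 3 for canola against shade without the dimmest array, is not among them. Canola to V8 gave 1 with log ratios, 221 with separate channels, 1 with the day term and 2 with quality weights. Shade to V8 gave 1 with quantile normalization, 11 with log ratios, 114 with separate channels and 3 with the day term. Canola removed and shade removed each gave 1 with separate channels. Canola kept against removed gave 2 with an offset of 0, 1 among brighter probes, 2 with log ratios, 168 with separate channels, 3 with the day term and 1 with quality weights. Shade kept against removed gave 33 with separate channels and 2 with the replicate block. Canola against shade, with 2, gave 1 without background subtraction, 0 with an offset of 0 or the plain mean, and 4 with loess alone, quantile normalization, brighter probes or log ratios. It gave 144 with separate channels, 8 with the replicate block, 7 with the day term and 7 with quality weights. Canola against low nitrogen, with 1, gave 0 without background subtraction, with an offset of 0, with log ratios and with the plain mean, and 7 with separate channels, which treats labellings as independent. The fit on log ratios likewise treats the 2 arrays of a sample as independent.

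Counts of lists past the threshold that moved by over 1.5 times were as follows; of smaller moves, 26 were to a higher and 6 to a lower count, and those of shade to V8, with 6, ran from 5 to 8. With the estimated correlation 0 passed in the 7 comparisons that had calls. Canola to V8, with 3, gave 5 with log ratios, with the replicate block, without the dimmest array and with quality weights. Low nitrogen, with 0, gave 3 with loess alone, 1 among brighter probes, 3 with the replicate block, and 1 without the dimmest array or with quality weights. Canola removed, with 0, gave 1 among brighter probes and without the dimmest array. Shade removed, with 1, gave 4 among brighter probes, 2 with bad spots kept and 3 with quality weights. Canola kept against removed, with 2, gave 6 with the plain mean. Shade kept against removed, with 4, gave 2 with an offset of 0 and without the dimmest array, and 8 with the replicate block. Canola against shade, with 5, gave 2 with an offset of 0, 3 with log ratios, 10 with the plain mean and 12 with the replicate block. Canola against low nitrogen, with 2, gave 1 with log ratios, 5 with the plain mean and 6 with the replicate block. Markers of other cell types against control, with 0, gave 1 without background subtraction, among brighter probes, with log ratios, without the dimmest array and with quality weights. The replicate block changed no call beyond those printed beside the results.

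With each biological sample left out in turn, probe counts ranged from 0 to 2 for canola to V8, 0 to 11 for shade to V8, 0 to 0 for low nitrogen, canola removed, shade removed and the overlap. They ranged from 0 to 1 for canola kept against removed, 0 to 4 for shade kept against removed, 0 to 12 for canola against shade and 0 to 1 for canola against low nitrogen. List counts ranged from 3 to 6 for canola to V8, 4 to 8 for shade to V8, 0 to 3 for low nitrogen and 0 to 4 for each stress removed at V4. They ranged from 2 to 3 for canola kept against removed, 2 to 9 for shade kept against removed, 2 to 8 for canola against shade, 1 to 4 for canola against low nitrogen, and from 0 to 2 for markers of other cell types against control. The highest probe counts came without shade to V8 replicate 2 for shade to V8 against control and for canola against shade, and without its replicate 3 for shade kept against removed.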

Other observations

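The tests of the authors' value table were chosen only after the result was seen; the adjustment over a list alone was planned. The patterns described here were picked after the values were seen, although the fixed rule names some of their probes too. Of the 4 probes annotated as early light-induced proteins, MZ00014983 had -0.71 ± 0.26 with shade to V8 (SE, n = 3 per group; limma, adjusted p = 1), beside -2.12, -1.44 and -0.79 for MZ00019578, MZ00041757 and MZ00036421. In the other 4 stresses the values ran from -0.85 to -0.65 for MZ00019578 and from -0.77 to -0.12 for MZ00041757. They ran from -0.37 to 0.061 for MZ00036421 and from -0.45 to 0.31 for MZ00014983. All 5 comparisons share the same 3 control samples, so a shared sign is no independent evidence, and over all probes 0 of these values passed by limma, the lowest adjusted p being 0.25. Members of the antioxidant list went both ways with shade to V8 when adjusted over the list alone, 3 up and 3 down. The ascorbate peroxidase (MZ00003968), chloroplast thioredoxin M (MZ00026938) and monodehydroascorbate reductase (MZ00041790) had 0.65 ± 0.16, 0.64 ± 0.15 and 0.88. Another ascorbate peroxidase (MZ00023500), cytosolic superoxide dismutase 4 (MZ00024194) and superoxide dismutase 4A (MZ00024195) had -0.52 ± 0.13, -0.79 ± 0.17 and -0.85 (limma, adjusted p over the list from 0.0194 to 0.0249).

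With canola kept to V8 against canola removed at V4, 6 photosystem probes were higher and 1 lower when adjusted over the list alone, while the list itself did not pass (median -0.003, limma camera, adjusted p = 0.617). PsaB (MZ00034839), saturated in 2 channels with canola kept to V8, had 1.08 ± 0.17, psaC (MZ00033552) 1.35 ± 0.31, and psaI (MZ00034841) 1.65 ± 0.43. Values were 1.26 ± 0.29 for photosystem I subunit IX (MZ00034842), 1.77 for psbH (MZ00034849) and 0.65 ± 0.18 for the nuclear-encoded subunit N (MZ00035161), while a thylakoid lumenal protein (MZ00021157) had -0.61 ± 0.17 (limma, adjusted p over the list up to 0.0424). The chloroplast 30S ribosomal protein S14 (MZ00034873) had 1.02 ± 0.21 (limma, adjusted p = 0.00664 over the chloroplast translation list alone). The 8 probes annotated as ketol-acid reductoisomerase or acetohydroxyacid isomeroreductase, the same enzyme, did not move together with canola to V8: MZ00013938 had -0.65 ± 0.13, MZ00021664 0.53 ± 0.19 and MZ00041711 0.57 ± 0.21.

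Columns of the authors' value table matched the scanner channels of other samples than their labels name: 2 of 36 columns correlated best with their own channel, and the median correlation with it was -0.042. A change of values by the authors' normalization was argued against, since the lowest correlation of a column with its best channel was 0.861. An attachment of columns to other samples would be consistent with 18 of 18 samples having both columns match best on 1 array, 17 of them 2 different channels of it. The tables argue against scanner files being attached to samples at random: arrays that share a sample by their labels should carry opposed log ratios, and their mean correlation was -0.157 against -0.045 for other pairs (18 pairs, one-sided permutation p = 3e-04). Since the labels put the 2 labellings of every sample on different arrays, the table's own naming of its columns is argued against as well. Whether every single scanner file is named correctly stays open, and no biological explanation was tested.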
